A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

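The series compared a newly induced histone H3 with one made all the time, along the yeast chromosomes. Per the labels, Saccharomyces cerevisiae of strain MDY510 carried a Flag-tagged H3 driven by a galactose promoter and a Myc-tagged H3 made all the time. The cells grew in 2% raffinose, were held in G1 with 4 µg/ml alpha factor, the mating pheromone, for 3 hours, and were moved to 2% galactose. Chromatin from each time point was immunoprecipitated with either anti-Flag or anti-Myc antibody, up to 75 ng of DNA was linearly amplified, and 3 µg of the amplified RNA was labelled. Both samples were hybridised together on printed arrays that cover a small part of the genome. There were 8 arrays, 1 each at 30 and 60 min after the move to galactose and 2 each at 90, 120 and 150 min. The labels number the replicates but do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

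The deposited scanner files give the intensity of each spot in the Cy5 and Cy3 channels, with the local background and the difference of the foreground median and that background, as computed by GenePix without any scanner normalisation, per the file headers. They also give the percent of saturated pixels per spot, per the file headers, and a mark for spots judged bad; spots with that mark were left out, and saturated spots were kept. A further table deposited by the authors holds 1 processed log2 ratio per probe and array. How the authors normalised it is not given in the sources used here. Set against log2 Cy3 over Cy5 of the scanner values, its slope was between 0.926 and 0.946 on 5 arrays and between -0.95 and -0.928 on the other 3. The median of its columns was 0.11 at 30 min, 0.28 at 60 min, 0.013 and 0 at 90 min, 0.22 and -0.26 at 120 min, and 0.063 and 0.16 at 150 min, for replicates 1 and 2 in turn. It has no value for 9119 probes at 30 min. Its exact scale and centring stay unknown, and it served only as an alternative, with its sign turned to read Flag over Myc and each array centred on its median.

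The direction of the ratio is likely but not settled. The labels put the Myc sample in Cy5 and the Flag sample in Cy3 on all 8 arrays. Taken that way, arrays fell into 2 sets that ran opposite to each other, with Pearson r between -0.788 and -0.494 over the probes. The sets are also the 2 scan sessions, which differed in scanner settings and scan day and are called scan batch 1 (30 and 60 min, 90 min replicate 2, 120 min replicate 1 and 150 min replicate 2) and scan batch 2 (90 min replicate 1, 120 min replicate 2 and 150 min replicate 1). Per the file headers, the 5 arrays of scan batch 1 were dye-swapped, and those of scan batch 2 carry no such remark. The ratio was therefore taken as Cy3 over Cy5 on the 3 arrays of scan batch 2 and as Cy5 over Cy3 on the other 5, so that it reads as Flag over Myc. With that turn every array correlated positively with every other, with r between 0.494 and 0.788 across batches. The table deposited by the authors then runs opposite on all 8 arrays, as the wording of the sample descriptions (Myc over Flag) would have it. The plain ratio of Cy3 over Cy5 fixed at the outset was thus kept for 3 arrays only. This direction was settled after the values of the feature classes had been seen with the sign the other way round. Each comparison is given with the sign turned as well, and dye orientation, scanner settings and scan day cannot be told apart.

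Probes are 50 bases long and were placed by their sequences and their numbering. They overlapped into 219 contigs with a step of 20 bases and 505770 bases in all, and 432 further spots are empty. The box held a gene table of assembly R64 and no genome. The probe numbers were tied to chromosome positions through open reading frames (ORFs) whose lengths and places match that table. Of the contigs, 160 were then placed by their own reading frames and 57 took the shift of the nearest placed contig. In this way 217 contigs with 24856 probes were tied to 15 chromosomes, and 2 contigs were left out. Chromosome III holds 13948 probes in 31 contigs. Of 442 annotated start codons inside the contigs, 420 were read as ATG. The placement itself favoured shifts with an ATG there, so this count is not a separate check. A reading frame was found for 327 of the 521 protein genes that overlap the contigs. As the build of the array is not given in the sources used here, no coordinates are printed, and regions are named by gene and neighbours. Replication origins, centromeres (CEN3 among them) and retrotransposon repeats are not in that table and were not analysed here. The MAT locus, GAL1, GAL10 and GAL7 had no region with enough probes measured.

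For each array the log2 ratio of the background-subtracted medians was computed where both were above 0, and was centred on the median of the array, without loess. A value of 0 is therefore the median probe, and a change with time is relative to it. Regions were promoters (up to 500 bp upstream of a start codon, ended at the next annotated gene), ORFs from start to stop codon, and tRNA genes with 100 bp on each side. A region entered with at least 3 probes measured on all 8 arrays, and its value was the mean of those probes. Divergent genes with the same set of promoter probes were merged under both names. Promoters that overlap only in part stayed separate and can share probes. Probe classes for the comparison with mid-ORF probes (over 500 bp from both ends of an ORF) needed at least 5 probes.

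Region values were fitted with limma (version 3.58.1 in R 4.3.3), with time as a linear term centred on its mean. The intercept is called the level and the slope is given per 60 min. For 150 against 30 min and 150 against 90 min, time was a factor, and the lone 30 and 60 min arrays were assumed to vary like the others. Tests were two-sided with a Benjamini-Hochberg threshold of 0.05 over all regions. Differences between probe classes were tested with an exact sign-flip permutation test over arrays, and correlations with time with exact permutations over the 40320 orders of 8 arrays. Within scan batches the times were permuted in all 720 ways. Gene lists with at least 5 measured promoters or ORFs were tested with limma's camera at its preset correlation of 0.01, beside camera with an estimated correlation and fry. The lists covered pheromone response, the galactose regulon, glycolysis and fermentation, ribosomal proteins, histones, heat shock and stress, amino acid and nitrogen metabolism, G1/S and cell cycle genes, meiosis and sporulation, and the silent mating cassettes with their neighbours. Figures were drawn with matplotlib 3.10.9 from tables written with pandas 2.3.3.

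The classes, tests, lists and rules for naming regions were fixed before the data were examined. Named were the 10 regions with the highest and the 10 with the lowest level among those called and on 1 side of 0 on all arrays, up to 6 called changes each way or the 3 largest where fewer than 3 were called, loci chosen for their known biology, and up to 4 members of each list, the 2 highest and the 2 lowest. Alternatives fixed at the same time were the signal without background subtraction, normexp (offset 50), loess, quantile scaling, the authors' table, only probes 2 background SDs above background, all spots kept, regression on probe GC content, medians for means, at least 6 probes, 200 bp promoters, other models of time, treat against a 1.2-fold ratio, the replicate number as a block, only 90 to 150 min, each array left out, and the 2 arrays farthest from the median time left out, a place for which 3 arrays tie. Fits with scan batch as a block, fits within a scan batch, and arrays scaled to 1 median absolute deviation were added after seeing the data.

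The fits were tested on simulated data with 200 of the 691 regions changed by known amounts. Noise was drawn independently for each region and array, with the spread of the fit's residuals. A shift between scan batches was added only to the data fitted with scan batch as a block. The level recovered 88.4% of changes of 0.5 and 99.0% of changes of 1 on the log2 scale, with 7 false calls among 491 unchanged regions. For slopes of 0.5 and 1 per 60 min the slope fit recovered 66.3% and 92.4%, and 91.6% and 100% with scan batch as a block. For differences of 0.5 and 1 the contrast of 150 with 30 min recovered 1.1% and 37.1%, and 9.5% and 79.0% with the block. That of 150 with 90 min recovered 13.7% and 61.9%. The shares of the slope and of the contrasts are therefore not for changes of equal size. Real regions can shift together between scan batches, so these shares may not hold for the real fits. The number of arrays limited the precision.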

Results

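The data set follows the ratio of Flag-H3, made only after galactose was added, to Myc-H3, made throughout, in yeast held in G1 by alpha factor. Each of the 8 arrays measured both histones at once, at 30 min (1 array), 60 min (1), 90 min (2), 120 min (2) or 150 min (2). Between 10.9% (90 min replicate 1) and 38.7% (30 min) of the 24960 probes were marked bad on an array, and 12360 probes, 49.5%, were measured on all 8. The loss was uneven between classes of probes. Of those measured on all 8 with bad spots kept, 1558 of 5610 promoter, 12 of 72 tRNA and 3112 of 4881 mid-ORF probes remained. The median background-subtracted signal was lowest at 30 min, at 771 scanner units in Cy5 against 4920 for 90 min replicate 1. In scan batch 1 (5 arrays) the SD of log2 ratios over probes lay between 0.52 and 0.78, and in scan batch 2 (3 arrays) between 1.01 and 1.08. Arrays of scan batch 2 correlated with each other at r of 0.956 to 0.964 over probes, those of scan batch 1 at 0.543 to 0.907, and arrays of different batches at 0.494 to 0.788.

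Positive values below stand for more Flag-H3 relative to Myc-H3 than at the median probe of the array, a direction that is likely, not settled. It rests on the dyes in the labels and on file headers that name a dye swap on the 5 arrays of scan batch 1. The table deposited by the authors runs opposite to it, as the wording of the sample descriptions (Myc over Flag) would have it. With the sign turned, each value below changes sign and each count above the median becomes one below it.

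The first question was where along genes the Flag/Myc ratio was high. Promoters stood above the middle of genes. Their 1558 probes had a mean log2 ratio of 0.60 ± 0.17 (SD, n = 8) and the 3112 mid-ORF probes one of -0.44 ± 0.18, a difference of 1.04 ± 0.34 that was positive on 8 of 8 arrays. Probes at tRNA genes, which are transcribed by RNA polymerase III, differed most from mid-ORF probes, by 1.63 ± 0.49, although only 12 probes stood for this class. With all spots kept, 72 tRNA probes differed by 1.38 and 5610 promoter probes by 1.06. Intergenic probes between convergent genes differed by 0.72 ± 0.25 (153 probes), the first 500 bp of ORFs by 0.61 ± 0.19 (4352 probes), and the last 500 bp by 0.45 ± 0.16 (2435 probes). Probes within 20 kb of an end of chromosome III, whatever their place in a gene, differed by 0.15 ± 0.09 (619 probes). Their own mean was -0.29 ± 0.20, below the median on 8 of 8 arrays. The 31 probes in the silent mating cassettes HML and HMR, which carry unexpressed copies of the mating-type genes, were close to mid-ORF probes. They differed by -0.02 ± 0.21, with 4 of 8 arrays on each side. Their own mean was -0.46 ± 0.33, below the median on 8 of 8 arrays. The means of the first and last 500 bp of ORFs were 0.16 and 0.01. Whether cassette probes also measured the MAT locus was not tested.

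The exact sign-flip permutation test gave p = 0.00781 for each of the classes but the cassettes, the smallest value that 8 arrays allow, and an adjusted p of 0.00911 over the 7 classes. For the cassettes the exact p was 0.758. Within scan batch 1 the promoter difference was 0.83 and within scan batch 2 it was 1.40. In the same order tRNA probes gave 1.48 and 1.89, and convergent intergenic probes 0.59 and 0.95. The first 500 bp gave 0.48 and 0.81, and the last 500 bp 0.34 and 0.63. The ends of chromosome III gave 0.17 and 0.12, and the cassettes 0.09 and -0.21. Neither batch alone can reach 0.05, since 5 arrays allow an exact p of 0.0625 and 3 arrays 0.25. With the sign turned, promoters lay at -1.04, tRNA probes at -1.63 and convergent intergenic probes at -0.72 against the middle of genes. The first and last 500 bp of ORFs then lay at -0.61 and -0.45, and the ends of chromosome III at -0.15.

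**Figure D1:**
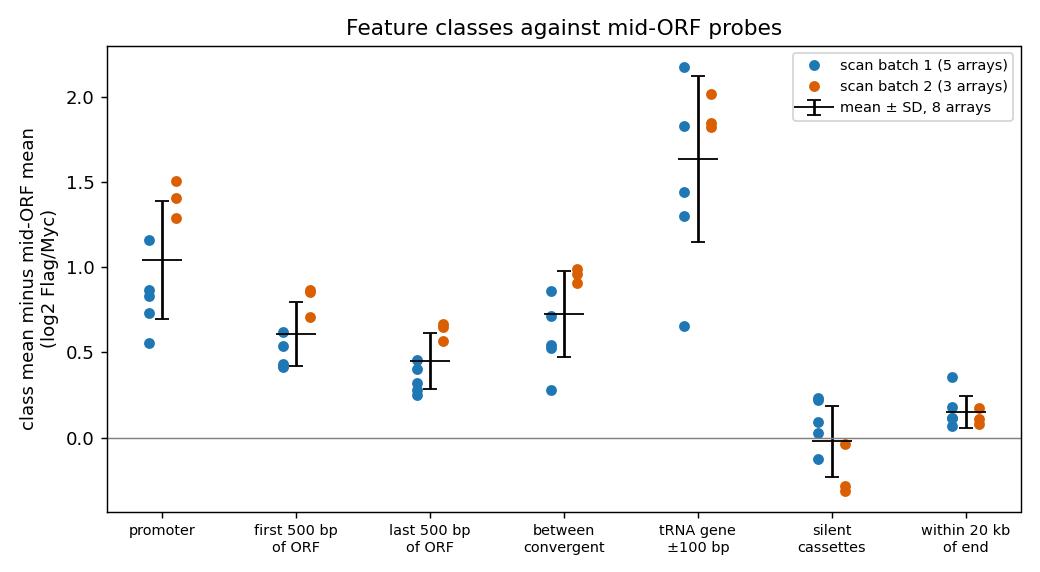
Difference in mean log2 (Flag/Myc) between each class of probes and mid-ORF probes, in log2 units, with 1 point per array coloured by scan batch and the mean over 8 arrays. Promoter probes (mean 1.04) and tRNA probes (mean 1.63) lie above 0 on every array, and cassette probes (mean -0.02) lie on both sides.

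Around start codons the ratio formed a hill over the promoter. Averaged in 100 bp bins, it was 0.14 ± 0.06 in the bin from 1000 to 900 bp upstream, stood at 0.50 ± 0.12 between 300 and 200 bp upstream, and was highest at 0.55 ± 0.16 and 0.55 ± 0.15 in the bins from 200 to 100 and from 100 to 0 bp upstream. The first 100 bp downstream of the start codon still stood at 0.47 ± 0.12. From 300 bp downstream onward the mean lay below 0, and it was -0.12 ± 0.12 between 500 and 600 bp. Each bin took every probe at its distance, including probes beyond the end of the gene or in a neighbouring one. The downstream values are therefore not those of ORF probes alone. The last 100 bp before the start codon averaged 0.46 in scan batch 1 and 0.72 in scan batch 2. This profile was descriptive and not tested, and with the sign turned it is a trough of -0.55.

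**Figure D2:**
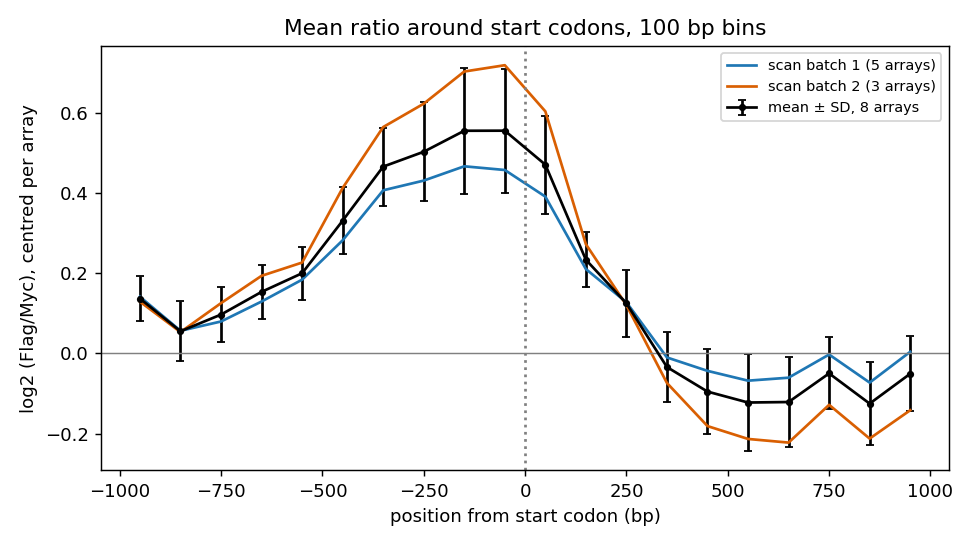
Mean log2 (Flag/Myc) in 100 bp bins against position from the start codon in bp, with the mean and SD of 8 arrays and the mean of each scan batch. The hill peaks at 0.55 just upstream of the start codon. Between 500 and 600 bp downstream of it the curve lies at -0.12, over all probes at that distance, inside the ORF or not.

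At the scale of single regions, most promoters stood above the array median, and ORFs split between both sides. Of 241 promoters, 179 were above, 16 below and 46 not called. Of 449 ORFs, 174 were above, 149 below and 126 not called. The mean level was 0.60 for promoters and 0.14 for ORFs. In 199 of 258 genes with both measured, the promoter was higher than its own ORF, with a median difference of 0.37, and the levels of both correlated across genes (Pearson r = 0.653, Spearman rho = 0.587), although genes are not independent replicates. In limma's fit over all 691 regions 354 were above and 165 below (534 at an unadjusted p under 0.05), and 300 of the former and 126 of the latter lay on the same side on all 8 arrays. The turned sign gives 165 above and 354 below. With scan batch as a block there were 382 above and 201 below, within scan batch 1 alone 335 and 150, and within scan batch 2 alone 377 and 223.

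The promoter of AGP1 on chromosome III, which encodes a broad-range amino acid permease, had the highest level, 2.72 ± 0.76 (SD, n = 8 here and below; 17 probes). The ORF of HIS3, a histidine biosynthesis gene, followed at 2.43 ± 0.84. Both regions of SDH6, an assembly factor of succinate dehydrogenase that lies beside ARO10, stood high, the promoter at 2.42 ± 0.70 and the ORF at 2.33 ± 0.72, although the SDH6 promoter level was 1.34 with all spots kept. The promoter and ORF of YCR006C, which lies between CIT2 and the proline tRNA gene SUF2, had levels of 2.40 ± 0.49 and 2.37 ± 0.75. The ORF of SHR5, a subunit of a protein palmitoyltransferase, was at 2.42 ± 0.48, the promoter of YCR024C-B at 2.24 ± 0.90, the ORF of MPC3, part of the mitochondrial pyruvate carrier, at 2.13 ± 0.63, and the promoter of SPL2, a regulator of phosphate uptake, at 2.09 ± 0.58. The promoters of SDH6, YCR024C-B and SPL2 and the ORF of SHR5 rested on 3 probes each. The ORFs of HIS3 and MPC3 rested on 5 probes each and that of SDH6 on 7, so such a value may stand for only part of an ORF. The largest limma adjusted p among these regions was 3.19e-05. They become the lowest regions with the sign turned.

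The lowest regions were mostly ORFs. KIN82 on chromosome III, a protein kinase gene, had the lowest level, -0.94 ± 0.37 over 75 probes. EMA35 near the right end of that chromosome was low over its promoter (-0.93 ± 0.40) and ORF (-0.91 ± 0.43), as was the promoter of its neighbour YCR099C (-0.85 ± 0.43). The ORFs of YOL162W (-0.84 ± 0.46), of RMA1 (-0.83 ± 0.23), of BSC5 (-0.79 ± 0.40), of DSC2, part of a membrane ubiquitin ligase (-0.79 ± 0.40), of PAT1, an mRNA decapping activator (-0.78 ± 0.47), and of PFF1, a vacuolar membrane protease (-0.78 ± 0.41), completed the set. The largest limma adjusted p among these was 0.00107. They become the highest regions with the sign turned.

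**Figure D3:**
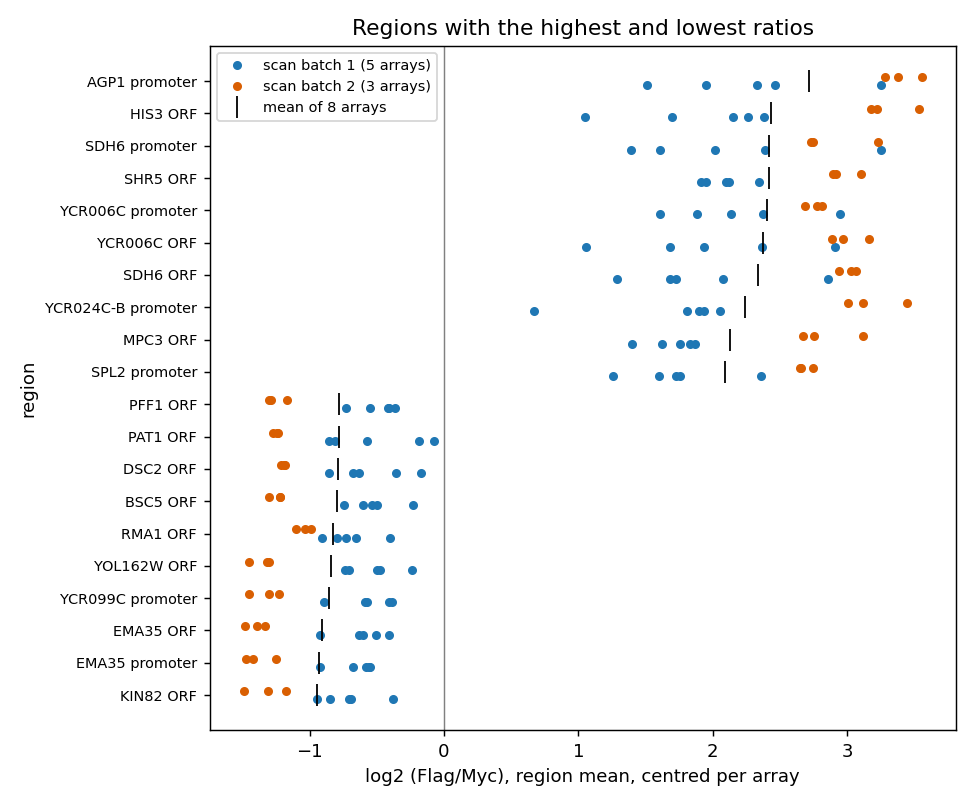
Level of the 10 highest and 10 lowest regions, as region mean log2 (Flag/Myc), with 1 point per array coloured by scan batch and the mean of 8 arrays. AGP1's promoter leads at 2.72 and KIN82's ORF is last at -0.94.

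Loci chosen for their known biology lay on both sides of the median. The ORF of PGK1, a phosphoglycerate kinase gene of glycolysis, was at 1.49 ± 0.68 (adjusted p = 9.94e-05) and the single measured tRNA region, SUF2, at 1.53 ± 0.63 (adjusted p = 3.19e-05). The promoters of LEU2, a leucine biosynthesis gene (1.44 ± 0.46), and of CIT2, a citrate synthase gene (1.62 ± 0.72), stood above their ORFs (0.31 ± 0.16 and 0.78 ± 0.12). The ORFs of HIS4, of histidine biosynthesis, and of CHA1, a serine and threonine deaminase, were not called (-0.11 ± 0.26 and 0.11 ± 0.38), while the promoter CHA1 shares with VAC17 was at 0.52 ± 0.38. HSP30, a stress protein gene, was low over its ORF (-0.46 ± 0.17). At the silent cassettes the ORF of HMLALPHA1 was at -0.53 ± 0.40, that of HMRA1 at -0.35 ± 0.28 and the promoter of HMRA1 at -0.74 ± 0.47. The promoter shared by HMLALPHA1 and HMLALPHA2 was not called (-0.17 ± 0.28). The cassettes hold copies of mating-type genes, and whether their probes also measured the MAT locus was not tested. Within scan batch 2 alone LEU2's ORF was not called (0.13), within scan batch 1 alone HMRA1's ORF was not called (-0.19), and with the sign turned every value here changes sign.

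Gene lists also held regions on both sides, and several were too short to test as sets. All 3 glycolysis regions were above the median, with the ORF and promoter of the glucokinase gene GLK1 at 1.204 ± 0.30 and 0.55 ± 0.42 beside PGK1, and so was the 1 ribosomal protein region, the ORF of RPL28 (1.33 ± 0.86). Of 17 regions of amino acid and nitrogen genes, 13 were above and 2 below, with HIS3's ORF and the promoter it shares with MRM1 (1.75 ± 0.56) highest and the ORFs of TRP5 (-0.61 ± 0.22) and MET17 (-0.23 ± 0.12) lowest. All 3 heat shock and stress regions were below, namely HSP30's ORF and the promoter (-0.38 ± 0.17) and ORF (-0.20 ± 0.21) of GRE1, a stress-induced gene. In the galactose list both regions of LAP3, a cysteine aminopeptidase gene, were above (1.199 ± 0.27 and 0.41 ± 0.22) and the ORF of GAL4, the activator of the regulon, was below (-0.55 ± 0.20). Of 8 cell cycle regions 2 promoters, that of SVS1 (0.67 ± 0.33) and the one shared by PNP1 and CLB4 (0.56 ± 0.22), were above, and 3 ORFs were below, among them SIC1, an inhibitor of cyclin-dependent kinase (-0.46 ± 0.24), and POL2, a DNA polymerase (-0.36 ± 0.15). Of 5 meiosis regions the promoter (0.78 ± 0.20) and ORF (0.20 ± 0.14) of SPS18 were above, and the ORF of SPO22 (0.06 ± 0.16) and the promoter of SPS22 (0.02 ± 0.25) were among the 3 not called. No histone gene had a measured region. Of the 17 regions of the silent cassettes and their neighbours, 3 were above, among them the promoter of the permease gene GIT1 (0.64 ± 0.33), and 10 below, led by the promoters of YCR099C and HMRA1. With the sign turned, 2 regions of amino acid genes, 10 of the silent list and 3 of the stress list were above.

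Adjusted over the list alone, with promoters and ORFs pooled, the counts of all lists were as given. Adjusted over the 10 pheromone response ORFs alone, 1 was below in place of 2. As sets, the promoters of the silent list had a mean level of -0.12 against 0.63 for other promoters (7 regions, camera adjusted p = 0.000458), a call that was lost at an adjusted p = 0.0904 with an estimated correlation. Their batch values were called at camera adjusted p = 0.000442 in scan batch 1, 0.00494 in scan batch 2 and 0.000432 with the batch as a block, and each of these was lost too (adjusted p = 0.526, 0.527 and 0.295 with an estimated correlation). No other list was called by camera at the level, the lowest other adjusted p being 0.0869 for the 10 ORFs of the silent list (mean -0.35, adjusted p = 0.503 with an estimated correlation), which became 0.0223 with scan batch as a block (adjusted p = 0.306 with an estimated correlation). The 7 promoters of amino acid genes had a mean of 1.15 (adjusted p = 0.135), the 10 ORFs of that list 0.38 (0.19), and the 5 cell cycle ORFs -0.24 (0.135). With fry, which asks only whether the regions of a list lie on balance on 1 side of 0 and compares them with no other regions, the amino acid promoters and ORFs (adjusted p = 0.000275 and 0.000293) lay above, and the cell cycle ORFs (0.0178) and the ORFs of the silent list (0.0358) below. The promoters of the silent list (0.103) and the pheromone response ORFs (0.456) were not called by fry. The fry calls of the cell cycle and silent ORFs were lost within scan batch 1 (adjusted p = 0.0764 for both) and scan batch 2 (0.131 and 0.0882), without 120 min replicate 2 (0.055 and 0.0916) or 150 min replicate 1 (0.068 and 0.0953), and in the authors' table with its sign turned (0.356 and 0.112). The fry call of the silent ORFs was also lost without 90 min replicate 2 (0.0784) and with at least 6 probes (0.0654). It was lost too with the replicate number as a block (0.0607, and 0.0695 with the GC regression). The fry call of the amino acid ORFs was lost within scan batch 2 (0.0775) and with at least 6 probes (0.0654). With at least 6 probes, 7 ORFs of that list were left, with a mean of 0.08 against 0.04 for other ORFs. The call of GRE1's ORF (adjusted p = 0.0338) was lost without any 1 of 6 arrays, at values between -0.21 and -0.14, and the level of SPS18's ORF was not called in scan batch 1 alone (0.12).

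The pheromone response list, many of whose genes alpha factor is known to induce in cells of mating type a, was mixed over all arrays and split by scan batch. Over all arrays 7 of its 13 regions were above the median, 2 below and 4 not called. Highest were the ORF of TEC1, a transcription factor (1.53 ± 1.21), and the promoter shared by PRM1 and ERG24 (0.94 ± 0.36), and lowest were the ORFs of STE3, the a-factor receptor of the other mating type (-0.70 ± 0.18), and STE50, a signalling adaptor (-0.26 ± 0.30). KAR4, a karyogamy regulator, had an ORF level of 0.93 ± 1.03 and a promoter level of 0.45 ± 0.23, and FUS1, a cell fusion gene, one of 0.79 ± 1.02 (ORF) and 0.80 ± 0.44 (promoter). The ORF of FIG2, a mating adhesin, was not called (0.15 ± 1.03). As a set the 10 ORFs had a mean of 0.41 and were not called (camera adjusted p = 0.553). Of these regions, 2 were above and 7 below with the sign turned.

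Split by scan batch, which was done after the values had been seen, FUS1's ORF averaged 0.06 in scan batch 1 and 2.00 in scan batch 2, KAR4's 0.19 and 2.16, TEC1's 0.66 and 2.97, FIG2's -0.58 and 1.36, PRM1's -0.08 and 1.78, and SCW10's 0.37 and 1.79, while STE3's averaged -0.61 and -0.86 and STE50's -0.06 and -0.59. With time in the limma fit, 7 of the 10 ORFs were higher and 1 lower in scan batch 2, by 1.10 on average against 0.03 for the 439 other ORFs (camera adjusted p = 0.000327 over 4 lists, and adjusted p = 0.0492 with an estimated correlation). The call of FUS1's ORF over all arrays (adjusted p = 0.0339) was lost without 90 min replicate 1 (0.65, adjusted p = 0.0702), 120 min replicate 2 (0.62, 0.0924) or 150 min replicate 1 (0.58, 0.106), the 3 arrays of scan batch 2, and that of KAR4's ORF without 150 min replicate 1 (0.75, 0.0569). The call of STE50's ORF (adjusted p = 0.0451) was lost without 30 min, 60 min, 90 min replicate 1, 120 min replicate 2 or 150 min replicate 1, at values between -0.28 and -0.19.

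**Figure D4:**
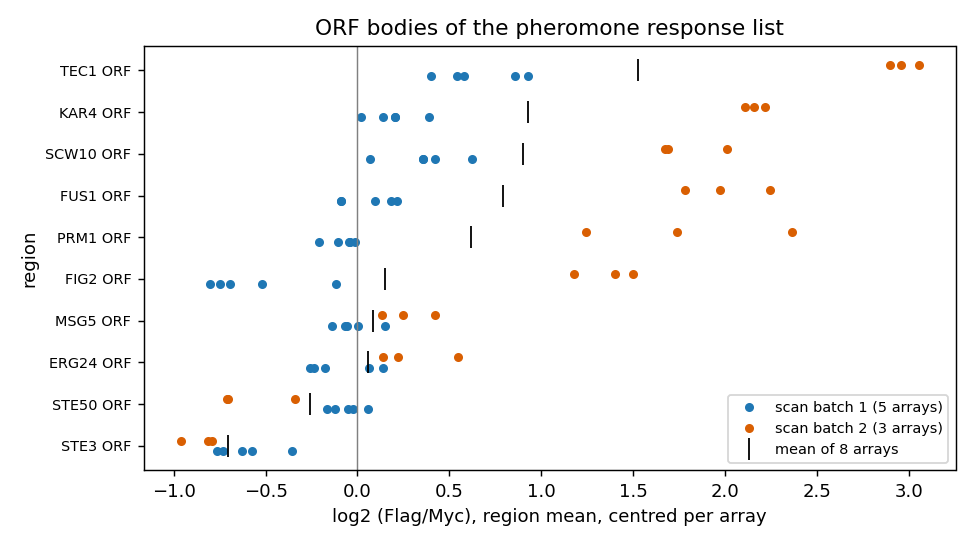
Region mean log2 (Flag/Myc) of the 10 measured ORFs of the pheromone response list, with 1 point per array coloured by scan batch and a bar for the mean of 8 arrays. FUS1 averages 0.06 in scan batch 1 and 2.00 in scan batch 2, and STE3 stays below 0 in both.

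The second question was whether the ratio of a region, relative to the median probe of its array, changed between 30 and 150 min. A change shared by all probes is removed by the centring and could not be seen. No region had a called slope in limma's fit over all arrays. Of 691 regions 0 rose and 0 fell, with 48 at an unadjusted p under 0.05 and a lowest adjusted p of 0.513. The 3 largest positive slopes per 60 min were 1.07 for the ORF and 1.02 for the promoter of YEL1, an exchange factor gene for a small GTPase (adjusted p = 0.758 for both), and 0.83 for the promoter of YCR024C-B (0.685). The 3 largest negative ones were -1.01 for the promoter shared by RNQ1, a prion protein gene, and BIK1, a microtubule-associated protein gene (0.513), -0.69 for the promoter of IMG1, a mitochondrial ribosomal protein gene (0.582), and -0.60 for SUF2 (0.685). YEL1's ORF also differed between the batches, at -0.16 in scan batch 1 and 2.94 in scan batch 2, and with the batch as a block its slope was 0.26 (adjusted p = 0.163).

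With scan batch as a block, 4 regions were called, and they are named here because they were called. The ORF and promoter of ARO10, a decarboxylase gene of amino acid breakdown, rose by 0.60 ± 0.08 (SE) and 0.59 ± 0.10 per 60 min (adjusted p = 0.00136 and 0.0111). The tRNA region SUF2 fell (-0.84 ± 0.10, adjusted p = 0.00107) and the promoter of BAP3, an amino acid permease gene, fell (-0.55 ± 0.11, adjusted p = 0.0392). Within the batches, the slopes were 0.58 and 0.72 for ARO10's ORF, 0.53 and 0.87 for its promoter, -0.95 and -0.34 for SUF2, and -0.56 and -0.52 for BAP3's promoter, in scan batches 1 and 2. Within scan batch 1 alone 1 region rose and 1 fell, and within scan batch 2 alone 11 rose and 0 fell (limma), although scan batch 2 has only 3 arrays. With the sign turned, rises and falls trade places.

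Gene lists changed little with time as sets. The 10 ORFs of amino acid and nitrogen genes had a mean slope of 0.20 per 60 min against 0.03 for the other ORFs (camera adjusted p = 0.0132), but the call was lost at an adjusted p = 0.266 with an estimated correlation. No member was called over all regions, 2 of the 10 ORFs were called when adjusted over the list alone, and none of the 17 regions was when promoters were included. With scan batch as a block the mean slope was 0.21 (adjusted p = 0.000763, and adjusted p = 0.245 with an estimated correlation), and it was 0.19 in scan batch 1 (0.000976) and 0.29 in scan batch 2 (0.0252), both lost as well (adjusted p = 0.7 and 0.804 with an estimated correlation). The call was lost without 150 min replicate 2 (mean 0.18, adjusted p = 0.114), with bright probes alone (0.07, 0.154) and with at least 6 probes per region (0.08, 0.183). The 10 pheromone response ORFs had a mean slope of 0.37 (camera adjusted p = 0.0686), which was 0.08 with scan batch as a block (0.453) and 0.04 in scan batch 1 alone (0.819). Within scan batch 2 alone this mean slope was 0.28 and called (0.0263, and adjusted p = 0.804 with an estimated correlation). The pheromone response ORF list, slope, was also called without 90 min replicate 1 (0.42, adjusted p = 0.0431) or without 150 min replicate 2 (0.60, 0.0314), both lost with an estimated correlation (adjusted p = 0.554 and 0.547 with an estimated correlation). It was at 0.18 without 150 min replicate 1 (0.362). Adjusted over the list alone, GLK1's ORF rose (0.31) and its promoter fell (-0.44) among the 3 glycolysis regions, and no region of the other lists was called when promoters and ORFs were pooled. The amino acid ORFs had a mean slope of -0.20 with the sign turned.

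The last time point was also compared with earlier ones. Between 150 and 30 min limma called 0 regions higher and 0 lower over all arrays (31 at an unadjusted p under 0.05), and the largest differences were -2.64 for the promoter of RNQ1 and BIK1 (adjusted p = 0.0946) and -1.77 for that of IMG1 (0.132). With scan batch as a block, 51 regions were higher at 150 min, 12 promoters and 39 ORFs, and 63 were lower, 32 promoters, 30 ORFs and SUF2. Among those higher were the promoters of YCR024C-B (1.39 ± 0.17, SE) and ARO10 (1.33 ± 0.17) and the ORF of HIS3 (1.29 ± 0.17), and among those lower the promoter of RNQ1 and BIK1 (-2.54 ± 0.17), that of IMG1 (-1.80 ± 0.17) and SUF2 (-1.70 ± 0.18). All of these calls rest on the single array at 30 min, which had the most bad spots (38.7%). Within scan batch 1 alone no test was possible because each time has 1 array, and scan batch 2 holds no 30 min array.

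Between 150 and 90 min, both with 2 arrays, limma again called 0 regions higher and 0 lower (1 at an unadjusted p under 0.05). With scan batch as a block, 9 regions were higher and 4 lower at 150 min, and all of these calls were lost when arrays were also scaled to 1 spread (0 higher and 0 lower in limma, 36 at an unadjusted p under 0.05). The higher ones included the ORFs of ATP1, a subunit of mitochondrial ATP synthase (0.97 ± 0.13, SE), GIP3, a phosphatase-interacting protein gene (0.76 ± 0.13), ARO10 (0.72 ± 0.13) and CHA1 (0.72 ± 0.14). The 4 lower ones were SUF2 (-0.66 ± 0.14) and the promoters of BAP3 (-0.57 ± 0.13), SDH6 (-0.55 ± 0.13) and AGP1 (-0.50 ± 0.14), and ATP1, GIP3, ARO10 and BAP3 are named only because they were called. The counts of both contrasts trade places with the sign turned.

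The contrast between parts of genes was also set against time over the 8 arrays. The difference of tRNA and mid-ORF probes had the largest correlation with time, Pearson r = -0.55 (exact permutation p = 0.16, Spearman rho = -0.594, exact p = 0.131), and it was not called, although rho was called with quantile scaling (-0.861, adjusted p = 0.0302). The promoter difference gave r = 0.086 (exact p = 0.834, rho = 0.036, exact p = 0.939), the difference of the first 500 bp r = 0.241 (exact p = 0.556, rho = 0.23, exact p = 0.581), and the SD over probes r = 0.153 (exact p = 0.713, rho = -0.036, exact p = 0.939). Over the 4 measures the adjusted p values were at least 0.639 for r and 0.525 for rho. The 30 min array lies farthest from the median time, and 60 min and both 150 min arrays tie for the next place, so each pair was left out, the pairs with 150 min added after seeing the data. Without 30 and 60 min r was -0.438 for tRNA probes, -0.241 for promoters, -0.102 for the first 500 bp and -0.085 for the SD. Without 30 min and 150 min replicate 1 the same measures gave -0.83, -0.567, -0.469 and -0.361, and without 30 min and 150 min replicate 2 they gave -0.389, 0.171, 0.259 and 0.348. None was called, the lowest adjusted p for r being 0.178. Within the 5 arrays of scan batch 1 the same measures gave -0.889, -0.489, -0.313 and -0.807 (exact p = 0.05, 0.417, 0.583 and 0.0833, and adjusted p = 0.167, 0.556, 0.583 and 0.167), and scan batch 2 holds 3 arrays. Without 30 min the promoter r was -0.238, and without 150 min replicate 2 it was 0.488. With the sign turned the class differences turn, so that r is 0.55 for tRNA probes, while the SD does not change.

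**Figure D5:**
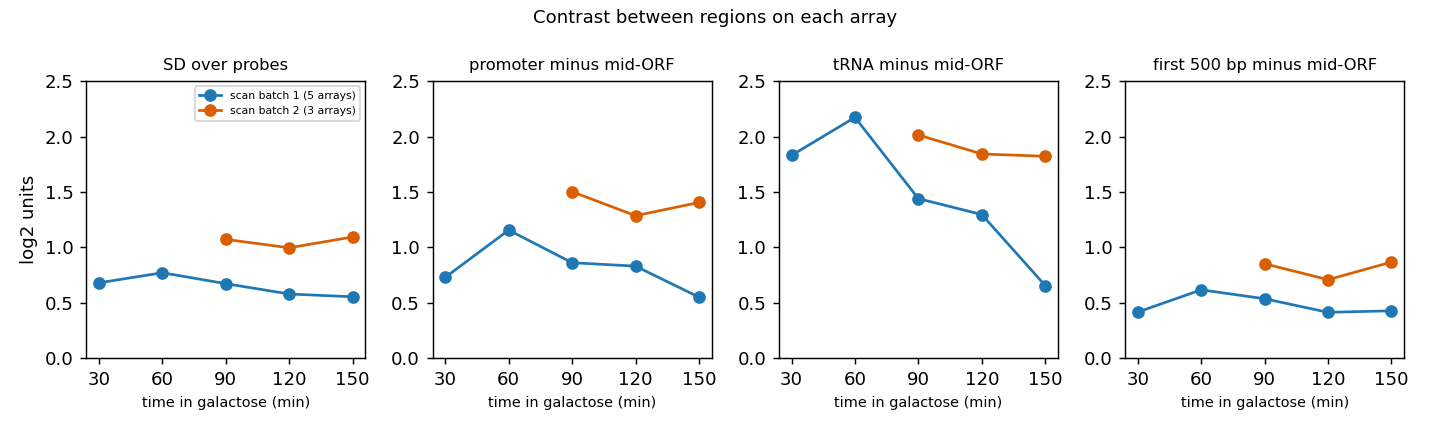
Each contrast measure, in log2 units, against time after galactose in min, with 1 point per array coloured by scan batch. Over 8 arrays r is -0.55 for the tRNA difference and 0.086 for the promoter difference.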

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

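The levels of regions and the differences between probe classes kept their sides under nearly all alternatives, and the counts of regions changing with time did not. Values with scan batch as a block, within a scan batch, with arrays scaled to 1 spread, or without 30 min and a 150 min array come from alternatives chosen after seeing the data. Values of the authors' table are given with its sign turned to Flag over Myc. Where a value moved, the cause was not tested unless the construction of the alternative shows it.

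Of 691 regions, 354 were above the median and 165 below, and leaving out any 1 array gave 335 to 357 and 155 to 180. Asking for at least 6 probes left 187 above, by construction, since it leaves out small regions such as many promoters. Testing against a 1.2-fold ratio left 85 below, again by construction. Among single regions, FIG2's ORF, not called over all arrays (0.15), was below the median within scan batch 1 (-0.58, limma adjusted p = 0.00025). The SPS22 promoter (level 0.02) was at -0.30 on the foreground without background subtraction, where limma called it.

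Promoter probes exceeded mid-ORF probes by 1.40 within scan batch 2 against 1.04 over all arrays, first-500-bp probes by 0.81 against 0.61, and last-500-bp probes by 0.63 against 0.45. The silent cassettes, at -0.02, crossed 0 in several settings without being called: 0.0017 with normexp, 0.0001 with quantile scaling, 0.0067 in the authors' table, 0.052 with all spots kept, 0.0040 after the GC regression, 0.0063 with arrays scaled and 0.10 (0.1036) with class medians. Leaving out 1 array gave -0.0595 to 0.0184 for the cassettes.

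No region had a called slope over all arrays or without any 1 array. Quantile scaling called 7 rises and 1 fall, scan batch as a block 2 and 2, the block with scaled arrays 9 and 2, scaled arrays 5 and 3, scan batch 1 alone 1 and 1, and scan batch 2 alone 11 rises. Between 150 and 30 min, quantile scaling called 3 regions higher, scan batch as a block 51 higher and 63 lower, the block with scaled arrays 59 and 58, scaled arrays 1 and 7, and bright probes alone 1 lower. Between 150 and 90 min, scan batch as a block called 9 higher and 4 lower, and the block with scaled arrays 0 and 0.

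The correlations of contrast with time changed sign in several settings, except for tRNA probes. For the SD over probes r was 0.153, and it became -0.175 with all spots kept, -0.404 with arrays scaled, -0.807 within scan batch 1, -0.085 without 30 and 60 min, -0.361 without 30 min and 150 min replicate 1, 0.348 without 30 min and 150 min replicate 2, and -0.129 to 0.464 without 1 array. Quantile scaling, which by construction makes the spread of arrays alike, gave 0.75 for the SD (exact permutation, adjusted p = 0.0591, and rho = 0.837, adjusted p = 0.0302). For promoters r was 0.086, and it became -0.113 with quantile scaling, -0.096 in the authors' table, -0.068 with all spots kept, -0.443 with arrays scaled, -0.489 within scan batch 1, -0.241 without 30 and 60 min, -0.567 without 30 min and 150 min replicate 1, 0.171 without 30 min and 150 min replicate 2, and -0.238 to 0.488 without 1 array. For the first 500 bp r was 0.241, and it became -0.313 within scan batch 1, -0.102 without 30 and 60 min, -0.469 without 30 min and 150 min replicate 1, 0.259 without 30 min and 150 min replicate 2, 0.479 with quantile scaling, and -0.051 to 0.511 without 1 array. For tRNA probes r was -0.55 and became -0.811 with quantile scaling (exact permutation, adjusted p = 0.0579, and rho = -0.861, adjusted p = 0.0302), -0.735 with normexp, -0.726 with loess, -0.706 in the authors' table and -0.912 with arrays scaled (exact permutation, adjusted p = 0.00873), and it was -0.713 to -0.332 without 1 array, the weakest without 150 min replicate 2.

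At the level, camera called 1 list over all arrays, 0 with at least 6 probes, 0 with bright probes, 3 in the authors' table, 2 with scan batch as a block, 2 with the block and scaled arrays, and 3 within scan batch 2. With an estimated correlation all of these calls were lost, the lowest adjusted p = 0.743, 0.295, 0.314 and 0.527 with an estimated correlation in the last 4 settings and 0.0904 over all arrays. The list called over all arrays, the promoters of the silent list, had too few members to be tested with at least 6 probes or with bright probes, and with all spots kept its call held (adjusted p = 0.0232 with an estimated correlation). For the slope it called 1 list over all arrays, 0 with at least 6 probes, 0 with bright probes, 2 in the authors' table, 2 with only 90 to 150 min, 2 within scan batch 2, and 1 to 2 without 1 array (2 without 90 min replicate 1). Every slope call was lost in every setting, replicate blocks included, the lowest being adjusted p = 0.0947 with an estimated correlation, after the GC regression. The second list called in the authors' table was the pheromone response ORFs (0.33, camera adjusted p = 0.00565, and adjusted p = 0.593 with an estimated correlation). The mean slope of the promoters of the silent list, -0.09 over all arrays, was 0.11 with only 90 to 150 min (camera adjusted p = 0.0107, and adjusted p = 0.233 with an estimated correlation).

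With the replicate number as a block 2 lists were called for the slope, and 2 with that block and the GC regression. They were the pheromone response ORFs, at 0.45 with the replicate block (camera adjusted p = 0.0401), and the amino acid ORFs. With an estimated correlation both were lost (adjusted p = 0.638 and 0.635 with an estimated correlation, and 0.55 and 0.238 with the GC regression). Deviations of replicate 1 from its time mean correlated at -0.908 between 90 and 120 min and at 0.928 between 90 and 150 min. Replicate 1 lies in scan batch 2 at 90 and 150 min and in scan batch 1 at 120 min. These values therefore cannot show whether the numbers pair samples.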

Other observations

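Pheromone genes were not the only ones to differ between the scan batches. Of 691 regions 225 were higher and 144 lower in scan batch 2, and with arrays scaled to 1 spread 58 were higher and 79 lower. The ORF of YEL1 averaged -0.16 in scan batch 1 and 2.94 in scan batch 2, that of YCR090C, beside FIG2 and KIN82, -0.40 and 2.29, that of the peroxisome gene PEX34 0.33 and 2.56, that of TRF5, a poly(A) polymerase gene, 0.17 and 2.06, and that of the kinase gene CLA4 0.32 and 2.15. In the silent list 9 of 10 ORFs were lower in scan batch 2, with a mean difference of -0.49 (camera adjusted p = 0.00373, and adjusted p = 0.266 with an estimated correlation). The tests on splits of the arrays, on orders of the times for 150 against 30 min and on bright probes were written before their results were seen, and the other tests below after the result was seen. Before the fit, 3 further tests on called slopes were written, and they were dropped because limma called 0 slopes (48 at an unadjusted p under 0.05).

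The higher ratio of pheromone response ORFs such as FUS1, KAR4 and FIG2 in scan batch 2 could come from biology, as stronger induction of these genes in the cells of those arrays, or from the arrays. A wider spread of ratios in that batch did not account for it, since the list still exceeded other ORFs by 0.85 after arrays were scaled to 1 spread, nor did probe GC content, with an excess of 1.07 after regression. Of the 56 splits of the arrays into 5 and 3, only 1, the scan batches, called as many as 369 regions, and the next called 204. Dye orientation in place of the cells could not be tested, because 0 scan batches hold both orientations. Arrays of 1 chromatin sample hybridised in both dye orientations would decide it.

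The difference of tRNA and mid-ORF probes was lower on the later arrays inside the scan batches in the 12 tRNA probes measured, with a partial r of -0.852. SUF2, whose 4 probes are among these 12, had a blocked slope of -0.84, so it is not a separate observation of that difference. A chance order of the times may account for this fall, as the exact permutation gave an adjusted p = 0.0889 over the 4 measures. That test was first set on the unadjusted exact p (0.0222) and moved to the adjusted one after that value was seen. With arrays scaled the adjusted p was 0.0333, so chance is neither excluded nor settled. A narrowing of all ratios with time did not, since the partial r was -0.905 with arrays scaled to 1 spread. More tRNA genes and more arrays per time would be needed.

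The 114 regions called between 150 and 30 min with scan batch as a block, among them the promoters of RNQ1 and BIK1 and of IMG1, may reflect the cells or the lone 30 min array. Of 100 orders of the times within batches 3, the real one included, called as many regions, and the highest other order called 130. Dim spots were not the whole account, since 62.5% of the 72 regions still measured with bright probes alone were called on the same side. A further 30 min array would be needed, as no test here separates that time from that array.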
